A study of Rattus norvegicus with 40 samples.

How the data were processed

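Gene expression was measured in the right ventricles of 24 male Sprague-Dawley rats in 4 groups of 6 animals, on 40 Agilent rat arrays with 2 colours. Per the labels, RNA of an animal was labelled with Cy5 and a common reference RNA, pooled from 14 rat cell lines, with Cy3, and this orientation was kept on every array. Each animal was hybridised on 1 to 5 arrays, which the labels number as technical replicates. Per the labels' protocols, 500 ng of total RNA per channel was amplified and labelled, and 825 ng of cRNA per channel was hybridised for 17 hours at 65 °C. Per the series' design text, images were read with GenePix Pro 5.0 and spots were normalised within each array by lowess with the marray package.

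The values used were the deposited normalised log ratios of sample over reference, which the authors gave per spot and array. They were read as log2 ratios: 1 deposited table is titled as log10, but its values ran from -13.6 to 14.0, a range that a log10 ratio of scanner intensities cannot span. The direction, sample over reference, was taken from the dyes. Array medians lay between -0.14 and 0.06, so the lowess left each array centred near 0. Background correction, spot filters and the reason for empty cells are not given in the sources used here, and 34.9% of the cells were empty. Intensities were not analysed here, so that saturation and signal over background could not be examined. The other deposited normalised table, with 45220 lines of which 43305 were matched, held the same values, apart from 1 cell of text.

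The array held 43379 spots, of which 74 were empty on every array. An annotation of the array named 1 gene for 25353 spots, several genes for 48 and none for 17978. Spots with several genes or none were left out of the gene tests. Of the spots with 1 gene, 25306 had their gene identifier in the reference gene table, through which 1 symbol was updated. Spots of a probe were averaged, giving 40941 probes, and the arrays of an animal were averaged, so that n counts animals. A probe was kept when at least 4 of the 6 animals of every group had a value, which left 21567 probes with or without a named gene. Probes of a gene were averaged, which gave 9775 tested genes, 6934 of them with 1 probe and 2841 with several; 6279 genes had a value in every animal.

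Linear models were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes) on the log2 ratios of all 24 animals with 1 mean per group, leaving 20 residual degrees of freedom and a prior of 2.44. All groups shared 1 estimate of the spread per gene. The comparisons were hypoxia against normal, SuHx against normal, SuHx against hypoxia, SuHx with carvedilol against SuHx and SuHx with carvedilol against normal. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes, two-sided. Errors given with a ± are the model's standard errors unless named as SD. The number of arrays and animals limits the precision: the median standard error of a difference between groups was 0.42 on the log2 scale.

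There were 33 lists of genes, 22 of pathways or functions and 11 of markers of cell types, written from general knowledge with 712 entries, of which 580 were tested. Each list was set against all other tested genes with camera at a preset correlation between genes of 0.01, and adjusted over the 33 lists of a comparison. Camera with a correlation estimated from the data was an alternative. The fry test asks whether a list's genes move on balance in 1 direction, without a comparison with other genes. List shifts were given relative to the mean of the other tested genes. Members were also adjusted over the list alone.

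The groups, comparisons, lists, tests, threshold, rule for named genes and other settings to be tried were fixed before the data were examined. Named genes in the first 4 comparisons were a fixed panel of 12 heart genes wherever tested, the 8 largest rises and the 8 largest falls among called genes with every animal on its own side of the other group's mean, leaving out placeholder symbols, and per list up to 4 members with the lowest adjusted p. A selection of these is printed. In comparisons that share normal or SuHx animals, the correlation and covariance of changes that shared animals bring were simulated with 100 random rotations of the residuals. Counts of shared or reversed genes in these simulations are not used, because the simulated comparisons called far fewer or far more genes than the real ones. For counts, the shared group was split into 3 and 3 animals in 20 ways. Measures of array quality were compared between groups with two-sided exact permutation tests over animals, adjusted over 10 tests.

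The code was tested on simulated data with the spread of the real animals, 9775 genes and 100 genes changed at each of 2 sizes. For hypoxia against normal, 71% of genes with a log2 change of 2 and 14% of those with a change of 1 were called, and 10.5% of calls were false. For SuHx against normal these values were 63%, 19% and 3.53%. For SuHx against hypoxia they were 69%, 17% and 7.53%. For SuHx with carvedilol against SuHx they were 62%, 16% and 2.5%, and for SuHx with carvedilol against normal 56%, 13% and 2.82%.

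Other settings tried were 3 further scalings between arrays (each array centred on its median, quantile normalisation, equal spread), the first technical array of each animal, all arrays with the animal as a random block (duplicateCorrelation with statmod 1.5.0), 2 other filters on empty cells, the probe with the highest mean ratio in place of the mean of probes, a test of probes, a trended and robust prior, animal weights, the replicate number as a block, animal numbers over 100 as a covariate or without the hypoxia animals that carry them, a minimum change of 1.5-fold, fits of only the 2 groups compared, and omission of each animal in turn. Random numbers used a fixed seed for each step.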

Results

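Right ventricles of 24 male Sprague-Dawley rats were profiled in 4 groups of 6 animals each. Normal rats breathed room air. Hypoxia rats breathed 10% oxygen for 4 weeks. SuHx rats received 1 injection of SU5416 (20 mg/kg), a blocker of receptors for vascular endothelial growth factor, then 4 weeks of the same hypoxia and 2 weeks at sea level. In the fourth group, SuHx rats were given carvedilol, a blocker of beta and alpha1 adrenergic receptors, at 15 mg/kg daily by gavage for 4 weeks after their return to room air. Time since hypoxia therefore differed between the groups, and no vehicle group was analysed here. In this field hypoxia alone is used as a model of an adapted right ventricle and SuHx as a model of a failing one, so the comparisons ask how the ventricle under each condition differs from normal, how the 2 loaded states differ, and what carvedilol changes. Normal animals had 8 arrays, hypoxia animals 12, SuHx animals 12 and carvedilol animals 8.

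Arrays of the groups did not hold the same number of values. Spots with a value ranged from 19264 to 35758 per array, with a mean per animal of 33254 (SD 2949) in normal, 26035 (SD 2092) in hypoxia, 28141.5 (SD 836) in SuHx and 28432 (SD 1852) in carvedilol animals. Hypoxia differed from normal with p = 0.00433 (two-sided exact permutation test, n = 6 per group, adjusted p = 0.00866) and carvedilol from SuHx with p = 0.766 (exact permutation test). The SD of the log ratios, 1.69 in normal animals, was 2.07 in hypoxia, 1.88 in SuHx and 1.98 in carvedilol animals, and 4 of the 5 comparisons had p = 0.00216 (exact permutation test, adjusted p = 0.00541), the smallest this design allows. Carvedilol against SuHx had p = 0.0368 (exact permutation test, adjusted p = 0.0409). Over 5413 probes, arrays of 1 animal correlated with a median r of 0.938 (27 pairs), arrays of different animals of a group with 0.909 (161 pairs) and arrays of different groups with 0.857. Within groups the median r between animals was 0.927 in normal, 0.865 in hypoxia, 0.929 in SuHx and 0.883 in carvedilol animals. On the first principal component (16.9% of the variance) hypoxia animals lay between 23.5 and 58.5 and all others between -24.8 and 6.37. On the second (14.5%) carvedilol animals lay between -56.3 and -13.5 and normal animals between 16.3 and 33.1.

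Gene changes are differences of mean log2 ratio, given with their SE and the adjusted p of the limma fit, with 6 animals per group unless another number is named. Single animals are numbered here from 1 to 6 within their group, in the order of the animal numbers in the labels. Animal numbers over 100 are those of the labels and belong to all 6 carvedilol animals and to hypoxia animals 5 and 6. For every called gene printed with a value, all animals lay on their own side of the other group's mean except where stated. Genes were refitted without each animal of the 2 groups in turn, apart from members of a list beyond its 4 lowest adjusted p and list members in carvedilol against normal. Lists of genes are given by how many tested members rose or fell, and their shift is the mean log2 change of the list minus that of all other tested genes, because the median change of all genes was itself -0.39 in hypoxia against normal, -0.12 in SuHx against normal, 0.26 in SuHx against hypoxia, -0.20 in carvedilol against SuHx and -0.32 in carvedilol against normal. Under quantile normalisation these medians were -0.29, -0.11, 0.16, -0.14 and -0.25.

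After 4 weeks of hypoxia, genes that control mitochondrial biogenesis were lower than in normal ventricle. Ppargc1b, a coactivator of genes of energy metabolism, changed by -3.62 ± 0.47 (adjusted p = 6.01e-05). The muscle regulator Perm1 changed by -2.84 ± 0.64 (5 hypoxia animals, adjusted p = 0.00685) and the fatty acid receptor Ppara by -1.59 ± 0.34 (adjusted p = 0.00381). Of 18 tested biogenesis regulators, 7 fell (Ppargc1b, Perm1, Rxrg, Ppara, Polg, Esrra and Polrmt), none rose and 11 did not pass. Adjusted over the list alone, 9 fell. The regulators as a list had a shift of -0.69 (camera adjusted p = 0.0211, adjusted p = 0.769 with an estimated correlation). The call was lost without normal animal 5 (adjusted p = 0.0548), without hypoxia animal 6 (adjusted p = 0.0821) and on probes with values on every array (adjusted p = 0.591). The highest-ratio probes (adjusted p = 0.189) and animal numbers over 100 as a covariate ended it as well. Ppargc1a, the best known member of the family, had too few values to be tested.

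Part of the genes of fuel use fell as well. In fatty acid oxidation 8 of 27 members fell and Acadm rose, with 12 lower and 1 higher adjusted over the list alone. Ucp3, a mitochondrial carrier, changed by -2.09 ± 0.44 (adjusted p = 0.00336) and Acot1, which hydrolyses acyl-CoA, by -3.06 ± 0.75 (4 hypoxia animals, adjusted p = 0.0108). Acot1 moved to -1.91 without hypoxia animal 5 and lost its call with only the 2 groups fitted (adjusted p = 0.0827). Cpt1b, which brings fatty acids into mitochondria, changed by -1.21 ± 0.22 (adjusted p = 0.00121), but turned to 0.76 on its highest-ratio probe alone. In the tricarboxylic acid cycle 6 of 19 members fell, with 1 higher and 9 lower adjusted over the list alone. Among them were the aspartate aminotransferase Got1 (-2.43 ± 0.44, adjusted p = 0.00125) and Dlst (-0.84 ± 0.20, adjusted p = 0.00773, but -1.35 with equal spread). In oxidative phosphorylation 6 of 35 members fell, and 7 adjusted over the list alone. The complex I subunit Ndufv1 led them (-1.37 ± 0.27, adjusted p = 0.00246). Glycolysis had 3 of 25 members lower, Hk1, Aldoa and Gpi, with 1 higher and 8 lower adjusted over the list alone. Hk1, a hexokinase, changed by -2.46 ± 0.33 (adjusted p = 8.71e-05) and Aldoa, an aldolase, by -1.60 ± 0.26 (adjusted p = 0.000571). Against all other genes these 4 lists did not pass (camera adjusted p = 0.229, 0.1, 0.483 and 0.112).

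Some receptors and channels of the response to catecholamines and calcium fell in hypoxia. Of 23 adrenergic signalling genes 5 fell (Akap6, Adrb1, Adra1b, Grk6 and Adcy6), and 7 adjusted over the list alone (camera adjusted p = 0.1). Fry passed in 13 of 33 lists (here adjusted p = 2e-06). Adrb1, the main beta adrenergic receptor of cardiomyocytes, changed by -1.62 ± 0.40 (adjusted p = 0.00981). Adra1b changed by -1.33 ± 0.31 (adjusted p = 0.00817), but by 0.0051 on its highest-ratio probe. In calcium handling 3 of 16 members fell, and 5 adjusted over the list alone (camera adjusted p = 0.47). They were the calcium release channel Ryr2 (-4.33 ± 0.80, 4 hypoxia animals, adjusted p = 0.00162), the dyad protein Jph2 (-2.10 ± 0.52, 5 hypoxia animals, adjusted p = 0.0105) and the exchanger Slc8a1 (-1.43 ± 0.38, adjusted p = 0.0174). Of 11 ion channels and connexins Hcn2, Kcnh2 and Gja1 fell, with the same number adjusted over the list alone (camera adjusted p = 0.546). The pacemaker channel Hcn2 changed by -1.90 ± 0.38 (adjusted p = 0.0027).

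Of all 9775 tested genes 1125 fell, and some genes of vessels and growth were among them. Of 23 angiogenic ligands and receptors Aplnr and Vegfb fell, both also adjusted over the list alone (camera adjusted p = 0.978). The apelin receptor Aplnr changed by -2.79 ± 0.44 (adjusted p = 0.00037) and Vegfb by -1.31 ± 0.23 (adjusted p = 0.00111), while Vegfa, at -1.07 ± 0.42 (adjusted p = 0.101), did not pass. In the insulin and growth factor list Gsk3b, Mtor, Fbxo32 and Erbb2 fell and Irs1 rose, of 23 tested, with the same numbers adjusted over the list alone (camera adjusted p = 0.602). Mtor, the growth kinase, changed by -1.54 ± 0.30 (adjusted p = 0.00199) and the insulin receptor substrate Irs1 by 1.66 ± 0.38 (adjusted p = 0.00594).

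Few genes of load or of matrix were called in hypoxia alone. Of 15 stress and fetal genes Nppb and Nrap rose and Tnni1 fell, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.122). Nppb, the gene of brain natriuretic peptide, rose 2.83-fold (log2 SE 0.41, adjusted p = 0.0194), a call lost without normal animal 5 (adjusted p = 0.0503). Nrap rose by 1.32 ± 0.42 (adjusted p = 0.0415, but by 0.30 with equal spread), which was lost without any animal but normal 4, hypoxia 2 or hypoxia 4 (adjusted p up to 0.0903). Nppa (-0.21 ± 0.41, adjusted p = 0.788), Myh7 (0.72 ± 0.43, adjusted p = 0.285), Myh6 (adjusted p = 0.998) and Atp2a2 (-0.44 ± 0.17, adjusted p = 0.104) did not pass. Of 30 extracellular matrix genes Col5a1 and Fbln1 fell, also adjusted over the list alone (camera adjusted p = 0.47). Col1a1 stood at -0.11 ± 0.33 (adjusted p = 0.859). None of 24 cell cycle genes was called, nor adjusted over the list alone, but the list had a shift of 0.67 (camera adjusted p = 0.00396). Its adjusted p was 0.842 with an estimated correlation, 0.142 without the 2 hypoxia arrays with the fewest values and 0.064 on probes with values on every array. The cell cycle shift was 1.29 with quantile normalisation, 1.11 with equal spread and 0.42 without those 2 arrays.

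Markers of other cells moved with these genes in part. Of 10 smooth muscle and pericyte markers Mcam, Abcc9 and Smtn fell, and 4 adjusted over the list alone (camera adjusted p = 0.663). Of 16 macrophage markers the complement gene C1qc fell (-1.51 ± 0.37, adjusted p = 0.0096), also adjusted over the list alone. Of 13 fibroblast markers vimentin (Vim) fell (-1.14 ± 0.25, adjusted p = 0.00486, but -0.73 with quantile normalisation), also adjusted over the list alone. Of 9 atrial markers Dkk3 and Gja5 fell, and 5 adjusted over the list alone (camera adjusted p = 0.47). Of 6 mesothelial and epicardial markers Krt18 fell and of 7 erythroid markers Slc4a1, both also adjusted over the list alone. Krt18 turned to 0.17 under quantile normalisation. Of 9 adipocyte markers Lep rose, with 1 higher and 1 lower adjusted over the list alone. Of 17 endothelial markers Fabp4 rose (0.98 ± 0.21, adjusted p = 0.00428), also adjusted over the list alone, but turned to -0.10 with arrays scaled to equal spread. Extreme changes by the fixed rule included Nmnat1, an enzyme of NAD synthesis (-4.83 ± 0.93, adjusted p = 0.00206), and the urea transporter Slc14a1 (-4.36 ± 0.80, 4 hypoxia animals, adjusted p = 0.00166). Among the rises were Scyl2 (3.49 ± 0.81, 5 hypoxia animals, adjusted p = 0.0096) and the adhesion gene Nectin4 (3.19 ± 0.72, adjusted p = 0.00755).

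In all, 1212 of 9775 genes were called between hypoxia and normal, 87 higher and 1125 lower in hypoxia, and 2742 had an unadjusted p under 0.05. In 1086 of them every animal lay on its own side of the other group's mean. Quantile normalisation called 1466 genes, 18.8% of them higher against 7.18% before. With equal spread 204 of 1861 called genes were higher. The share was 12.8% on probes with values on every array and 10.9% without the 2 hypoxia arrays with the fewest values. Of genes named without values, Gja5 lost its call in 9 of 12 omissions, Kcnh2 in 7, Smtn in 5, Mcam, Gja1 and Fbln1 in 4, Tnni1 in 3 and Adcy6 in 1. Besides biogenesis regulators and cell cycle none of the 33 lists passed camera, and none passed with an estimated correlation.

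Abcc9, Adcy6, Adra1b, C1qc, Col5a1, Fabp4, Gja5, Irs1, Kcnh2, Lep, Nectin4, Ppara, Slc8a1, Smtn and Tnni1 lost their calls on the first technical array. Adcy6, Col5a1, Fbln1, Gja1, Gja5, Grk6, Kcnh2, Krt18, Nppb, Nrap, Slc4a1, Slc8a1 and Smtn did so with values of 2 animals per group. Abcc9, Adra1b, C1qc, Col5a1, Cpt1b, Dkk3, Fbln1, Gja1, Gpi, Hcn2, Mcam, Slc8a1 and Smtn did so on the highest-ratio probe. Acot1, Adcy6, Fbln1, Gja1, Gja5, Gpi, Grk6, Mcam, Nppb, Slc4a1, Smtn and Tnni1 did so with only the 2 groups fitted. C1qc, Col5a1, Fbln1, Gja1, Gja5, Gpi, Kcnh2, Lep, Nrap and Tnni1 did so with animal numbers over 100 as a covariate. Col5a1, Fbln1, Gja1, Gja5, Kcnh2, Lep, Nrap and Tnni1 did so without the hypoxia animals numbered over 100. C1qc, Fbln1, Fbxo32, Gja5, Kcnh2, Lep and Smtn did so with a random block. Fabp4, Krt18, Nppb and Nrap did so with equal spread. Gja1, Gja5, Nrap and Slc4a1 did so without the least correlated animals. Col5a1, Gja5 and Krt18 did so under quantile normalisation. Fbln1, Gja1 and Mcam did so on probes with values on every array. Calls also ended for Fbln1 and Mcam without the 2 hypoxia arrays, Fbln1 and Gja5 with animal weights, Slc4a1 and Tnni1 with the replicate number as a block, and Gja5 with arrays centred.

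**Figure D1:**
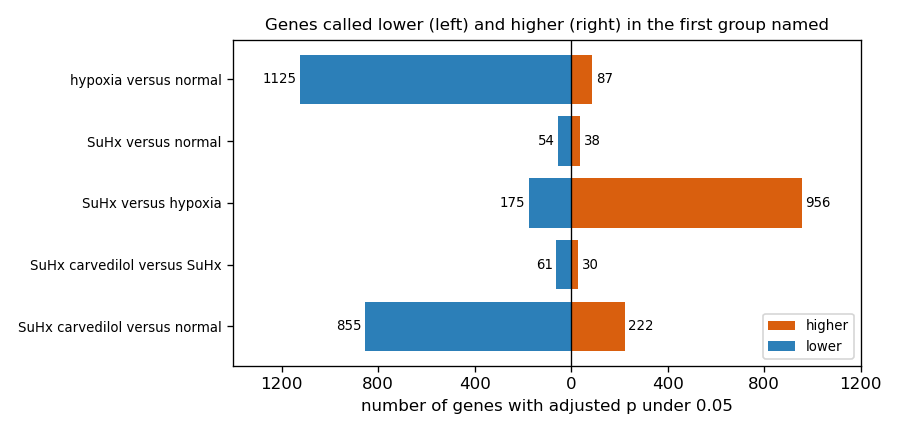
Number of genes called (adjusted p under 0.05) as lower or higher in each of the 5 comparisons, with bars starting at 0. Hypoxia against normal had 1125 lower and 87 higher genes, and SuHx against hypoxia 175 lower and 956 higher.

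SuHx ventricles held more RNA of matrix and stress genes than normal ventricles. Of 30 extracellular matrix genes 3 rose, and 10 adjusted over the list alone. Periostin (Postn), a matrix protein of activated fibroblasts, rose by 3.79 ± 0.64 (5 SuHx animals, adjusted p = 0.0062), Thbs4 by 3.49 ± 0.59 (adjusted p = 0.00578) and the connective tissue growth factor Ccn2 by 2.43 ± 0.36 (adjusted p = 0.00165). Ccn2 lost its call on its highest-ratio probe (1.64, adjusted p = 0.107). Matrix genes as a list had a shift of 1.05 (camera adjusted p = 5.05e-16, adjusted p = 0.084 with an estimated correlation). Of 15 stress and fetal genes 4 rose, and 7 adjusted over the list alone. They were Nppb (2.76 ± 0.41, adjusted p = 0.00165), Enah (1.67 ± 0.23, adjusted p = 0.000918), the calcineurin regulator Rcan1 (1.41 ± 0.23, adjusted p = 0.00563) and Fhl1 (1.31 ± 0.26, adjusted p = 0.0158). Fhl1 lost its call without normal animal 4 or SuHx animal 6 (adjusted p up to 0.0526). Stress and fetal genes as a list had a shift of 0.91 (camera adjusted p = 4.2e-10, adjusted p = 0.0102 with an estimated correlation).

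Macrophage markers stood higher beside these groups. None of 16 was called over all genes, 3 rose adjusted over the list alone, and the shift was 0.72 (camera adjusted p = 1.07e-07, adjusted p = 0.0211 with an estimated correlation). Fibroblast markers, 13 tested and none called, had a shift of 0.45 (camera adjusted p = 0.0287, adjusted p = 0.519 with an estimated correlation). That call was lost without normal animal 2 or 3 or SuHx animal 4, 5 or 6 (adjusted p up to 0.111). Of 6 mesothelial and epicardial markers the keratin Krt18 fell, and 2 fell adjusted over the list alone. Their shift was -0.77 (camera adjusted p = 0.0238, adjusted p = 0.234 with an estimated correlation), which was lost without normal animal 6 or SuHx animal 5 (adjusted p up to 0.0959) and moved to -0.37 without the latter. Krt18 itself changed by -0.82 ± 0.17 (adjusted p = 0.0243) and lost its call without normal animal 4 or 5 or SuHx animal 6 (adjusted p up to 0.0771). Of 10 smooth muscle and pericyte markers Rgs5 rose, also adjusted over the list alone (camera adjusted p = 0.666), a call lost in 4 of 12 omissions. Erythroid markers passed with no member called (shift 0.59, camera adjusted p = 0.0372, adjusted p = 0.208 with an estimated correlation). Endothelial markers did so too (shift 0.39, camera adjusted p = 0.0497, adjusted p = 0.564 with an estimated correlation). Erythroid markers lost their call without normal animal 1, 2, 5 or 6 or SuHx animal 4, 5 or 6 (adjusted p up to 0.116). Endothelial markers lost theirs without normal animal 1, 2, 5 or 6 or SuHx animal 2, 3, 4 or 6 (adjusted p up to 0.132).

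Sarcomere and some fuel lists moved in SuHx. Of 19 adult sarcomere genes none was called and 4 rose adjusted over the list alone, with a shift of 0.64 (camera adjusted p = 1.43e-06, adjusted p = 0.31 with an estimated correlation). Quantile normalisation ended that call (shift 0.25, adjusted p = 0.0515), and equal spread gave a sarcomere shift of 0.35. Of 27 fatty acid oxidation genes Decr1 fell, and 10 fell adjusted over the list alone, with a shift of -0.55 (camera adjusted p = 3.53e-06, adjusted p = 0.394 with an estimated correlation). Decr1 changed by -1.38 ± 0.33 (adjusted p = 0.0415, not in all animals) and lost its call without any animal but SuHx 5 (adjusted p up to 0.117). Of 35 oxidative phosphorylation genes Atp5po fell, and 3 fell adjusted over the list alone, with a shift of -0.23 (camera adjusted p = 0.00186, adjusted p = 0.644 with an estimated correlation). The shift moved to -0.11 and did not pass without SuHx animal 4 (adjusted p = 0.0813). It was -0.39 with quantile normalisation, -0.45 with equal spread, -0.41 with the animal as a random block, -0.095 on the first technical array of each animal and -0.15 without the least correlated animals. Atp5po changed by -1.20 ± 0.28 (adjusted p = 0.0415) and lost its call without any animal but SuHx 2 or 3 (adjusted p up to 0.117). Biogenesis regulators (shift -0.20, adjusted p = 0.233) and glycolysis (shift 0.28, adjusted p = 0.068) did not pass.

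A further 3 lists lay above the other genes with no member called. Ion channels and connexins (11 tested, 2 higher adjusted over the list alone) had a shift of 0.82 (camera adjusted p = 0.00426, adjusted p = 0.231 with an estimated correlation). Genes of the oxidative stress response (22 tested) had a shift of 0.36 (camera adjusted p = 0.00946, adjusted p = 0.387 with an estimated correlation). TGF-beta, BMP and matrix protease genes (26 tested) had a shift of 0.35 (camera adjusted p = 0.0205, adjusted p = 0.519 with an estimated correlation). The last call was lost without SuHx animal 4 or 6 (adjusted p up to 0.106), and that of ion channels under quantile normalisation (adjusted p = 0.0515). In the latter 2 lists no member passed adjusted over the list alone.

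The largest change was in Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor. Its mean log2 ratio was 6.21 (SD 1.12, n = 6) in SuHx and -1.97 (SD 0.72, n = 6) in normal animals. The difference was 8.19 ± 0.62 (limma adjusted p = 4.13e-08), measured by 1 probe. Other large rises by the fixed rule were those of Tceal7 (3.41 ± 0.61, adjusted p = 0.00691) and the protocadherin Pcdha4 (2.82 ± 0.45, 4 SuHx animals, adjusted p = 0.0062). Falls included the granzyme Gzmc (-4.12 ± 0.78, adjusted p = 0.0123) and Myoc (-4.13 ± 0.79, 4 SuHx animals, adjusted p = 0.0158), the latter lost without SuHx animal 5 (adjusted p = 0.0526). Of the fixed panel, Myh7 (1.25 ± 0.43, adjusted p = 0.172), Col1a1 (0.39 ± 0.33, adjusted p = 0.717) and Adrb1 (0.30 ± 0.40, adjusted p = 0.845) did not pass. Nor did Apln (-1.22 ± 0.34, adjusted p = 0.0857), Angpt1 (-2.93 ± 0.80, adjusted p = 0.0795) and Vegfa (-0.14 ± 0.42, adjusted p = 0.957).

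In all, 92 genes were called between SuHx and normal, 38 higher and 54 lower, with 1227 at an unadjusted p under 0.05. In 90 of them all animals lay on their own side. The count fell to 57, 46, 48, 31 and 38 without normal animal 1, 2, 3, 4 or 5 and to 58, 36, 45 and 36 without SuHx animal 1, 4, 5 or 6. Scaling to equal spread called 313 genes, 27.2% of them higher against 41.3% before. The share moved the other way to 92.9% of 14 genes on the first technical array, 64.5% of 31 without normal animal 4 and 90% of 10 without the least correlated animal of each group. Without SuHx animal 4 38.9% of 36 genes were lower, against 58.7% before.

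Atp5po, Decr1, Fhl1, Gzmc, Krt18, Myoc, Pcdha4, Rcan1, Rgs5, Tceal7 and Thbs4 lost their calls without the least correlated animals. Atp5po, Decr1, Fhl1, Gzmc, Krt18, Rcan1 and Rgs5 did so on the first technical array. Atp5po, Decr1, Enah, Krt18 and Postn did so with values of 2 animals per group, with Postn at 2.47. Atp5po, Decr1, Krt18 and Rgs5 did so with the replicate number as a block. Calls also ended for Pcdha4 and Rgs5 with a random block, Ccn2 and Fhl1 on the highest-ratio probe, Rgs5 with equal spread, Decr1 with only the 2 groups fitted, Krt18 under quantile normalisation, and Krt18 with a trended prior.

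The sarcomere, endothelial, erythroid, fibroblast, ion channel and mesothelial lists lost their calls under quantile normalisation. The TGF-beta, endothelial, erythroid, fibroblast and mesothelial lists did so with values of 2 animals per group. The TGF-beta, endothelial, fibroblast, ion channel and oxidative stress response lists did so on probes with values on every array. The TGF-beta, endothelial, erythroid, fibroblast and mesothelial lists did so on the highest-ratio probe. The TGF-beta, endothelial, fibroblast and oxidative phosphorylation lists did so on the first technical array. The endothelial, erythroid, fibroblast and mesothelial lists did so with equal spread. The TGF-beta, erythroid and mesothelial lists did so without the least correlated animals. The endothelial, erythroid and mesothelial lists did so with a random block. List calls also ended for endothelial and mesothelial with only the 2 groups fitted, endothelial with arrays centred, endothelial with the replicate number as a block, and fibroblast without the 2 hypoxia arrays.

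**Figure D2:**
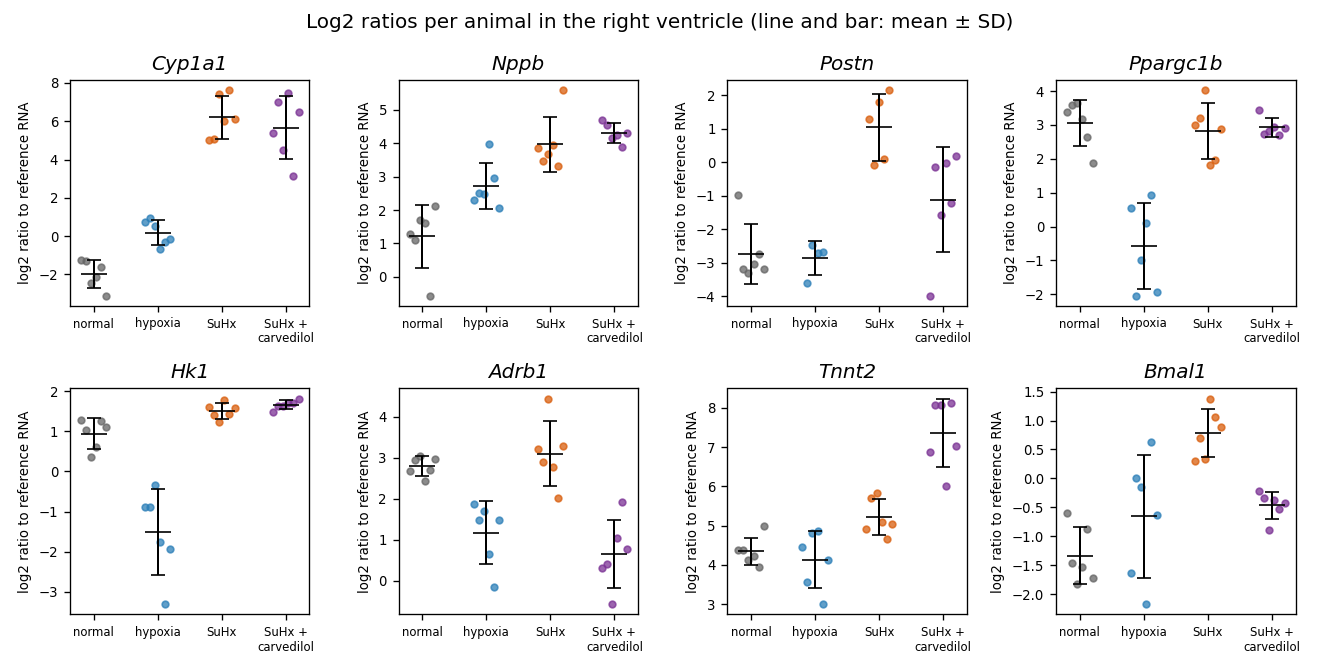
Log2 ratio of sample over reference in each animal (points) for 8 genes by group, with the group mean (line) and SD (bar). Cyp1a1 was higher in SuHx (mean 6.21) than in normal animals (mean -1.97).

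Set directly against hypoxia, the SuHx ventricle had more RNA of matrix, glycolytic, stress and excitation genes. Of 30 matrix genes 12 rose and none fell, with 19 higher and 1 lower adjusted over the list alone. Among them were Postn (3.92 ± 0.71, 5 SuHx and 4 hypoxia animals, adjusted p = 0.0016), the fibrillin binding gene Ltbp2 (3.62 ± 0.69, 5 hypoxia animals, adjusted p = 0.00197), Thbs4 (3.19 ± 0.59, adjusted p = 0.00137) and the collagen Col5a1 (1.77 ± 0.31, adjusted p = 0.00096). Their list shift was 0.88 (camera adjusted p = 2.26e-05, adjusted p = 0.492 with an estimated correlation), and 0.38 on the first technical array of each animal. Of 25 glycolytic genes 8 rose (Pgk1, Eno1, Gpi, Ldha, Pgam1, Pfkp, Aldoa and Hk1), and 9 adjusted over the list alone. Hk1 changed by 3.02 ± 0.33 (adjusted p = 6.1e-06, but by 1.83 with values asked of 2 animals per group), Aldoa by 1.63 ± 0.26 (adjusted p = 0.000485) and the lactate dehydrogenase Ldha by 1.13 ± 0.27 (adjusted p = 0.00841). Glycolysis as a list had a shift of 0.43 (camera adjusted p = 0.00654, adjusted p = 0.492 with an estimated correlation).

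Of 15 stress and fetal genes 6 rose in SuHx against hypoxia, and 7 adjusted over the list alone. They were led by Fhl1 (1.49 ± 0.26, adjusted p = 0.000918), Enah (1.19 ± 0.23, adjusted p = 0.00211) and Rcan1 (1.15 ± 0.23, adjusted p = 0.00287). The shift was 0.57 (camera adjusted p = 0.00688, adjusted p = 0.392 with an estimated correlation). Nppb was 1.26 ± 0.41 higher (adjusted p = 0.0485, not in all animals), a call lost without any animal but hypoxia 4 or SuHx 5 (adjusted p up to 0.131). Of 11 ion channels and connexins Hcn2, Kcnip2 and Cacna1g rose, and 5 adjusted over the list alone (shift 1.21, camera adjusted p = 0.0125, adjusted p = 0.392 with an estimated correlation). Hcn2 changed by 2.36 ± 0.38 (adjusted p = 0.000486) and Kcnip2, a subunit of transient outward potassium channels, by 4.18 ± 0.72 (4 SuHx and 5 hypoxia animals, adjusted p = 0.00108). Of 16 calcium handling genes Ryr2 (4.24 ± 0.80, 4 hypoxia animals, adjusted p = 0.00197) and Jph2 (2.25 ± 0.52, 5 hypoxia animals, adjusted p = 0.00706) rose, also adjusted over the list alone (camera adjusted p = 0.321).

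Of 23 adrenergic genes Prkar1a, Adrb1, Akap6 and Adcy5 rose, with the same number adjusted over the list alone (camera adjusted p = 0.123). Adrb1 changed by 1.93 ± 0.40 (adjusted p = 0.00325) and the adenylyl cyclase Adcy5 by 2.71 ± 0.44 (adjusted p = 0.000445). Of 18 biogenesis regulators Polg and Ppargc1b rose, and 4 adjusted over the list alone (camera adjusted p = 0.124), with Ppargc1b at 3.39 ± 0.47 (adjusted p = 9.15e-05). Of 19 genes of the tricarboxylic acid cycle Got1 rose (2.43 ± 0.44, adjusted p = 0.00122), and 3 adjusted over the list alone (camera adjusted p = 0.194). Aplnr was 2.28 ± 0.44 higher (adjusted p = 0.0018), one of 4 of 23 angiogenic genes that rose. Of 26 TGF-beta, BMP and matrix protease genes 5 rose and Ltbp1 fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.217). Eng, a TGF-beta co-receptor of endothelium, changed by 2.56 ± 0.48 (5 hypoxia animals, adjusted p = 0.00179) and the pathway inhibitor Smad7 by 1.70 ± 0.28 (adjusted p = 0.000612).

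Markers of other cells moved between these groups too. Of 16 macrophage markers Lyz2, Mrc1, C1qa and C1qc rose, and 7 adjusted over the list alone, with C1qc at 2.34 ± 0.37 (adjusted p = 0.000361). Macrophage markers as a list had a shift of 0.53 (camera adjusted p = 0.0125, adjusted p = 0.411 with an estimated correlation). Of 13 fibroblast markers Mfap4, Vim and Fap rose, and 4 adjusted over the list alone (camera adjusted p = 0.62). Of 9 atrial markers Dkk3, Myl7 and Gja5 rose, with the same number adjusted over the list alone (camera adjusted p = 0.348). Of 10 smooth muscle and pericyte markers Abcc9 and Mcam rose, also adjusted over the list alone (camera adjusted p = 0.304). Of 17 endothelial markers Cldn5 rose and Fabp4 fell, with 4 and 1 adjusted over the list alone (camera adjusted p = 0.544), and of 9 adipocyte markers Lep fell, also adjusted over the list alone. Of 8 lymphocyte markers Zap70 fell, and 2 fell adjusted over the list alone (shift -0.82, camera adjusted p = 0.0125, adjusted p = 0.23 with an estimated correlation). The list's call was lost without SuHx animal 6 (adjusted p = 0.0518). Of 24 cell cycle genes Mcm3 fell, and none adjusted over the list alone (shift -0.63, camera adjusted p = 0.00688, adjusted p = 0.567 with an estimated correlation). Mcm3 turned to 0.034 on its highest-ratio probe. Cyp1a1 was 6.04 ± 0.62 higher (adjusted p = 4.06e-06) and Gzmc changed by -4.12 ± 0.78 (adjusted p = 0.0019). Nppa (0.09 ± 0.41, adjusted p = 0.921), Myh7 (0.54 ± 0.43, adjusted p = 0.448), Atp2a2 (0.17 ± 0.17, adjusted p = 0.57) and Col1a1 (0.51 ± 0.33, adjusted p = 0.353) did not pass.

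Between SuHx and hypoxia 1131 genes were called, 956 higher and 175 lower in SuHx, with 2581 at an unadjusted p under 0.05. All animals lay on their own side in 1008 of them. Of the called genes 15.5% were lower, against 26.2% on probes with values on every array and 24.5% without the 2 hypoxia arrays with the fewest values. Among genes named without values, Akap6 lost its call in 10 of 12 omissions, Zap70 in 9, Lyz2, Cacna1g and Gja5 in 8, Mrc1 and Polg in 7, Mcm3 and Lep in 6, Mfap4 in 5, Mcam in 4 and Fabp4 in 1. The 7 list calls (matrix, glycolysis, cell cycle, stress, ion channels, macrophage and lymphocyte markers) were all lost on probes with values on every array, where matrix and glycolysis each had an adjusted p of 0.0657.

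Akap6, Cacna1g, Enah, Gja5, Lep, Lyz2, Mcm3, Mfap4, Mrc1, Nppb, Pgam1, Polg, Postn and Zap70 lost their calls with values asked of 2 animals per group. Abcc9, Akap6, Cacna1g, Fabp4, Gja5, Lep, Mcm3, Mfap4, Mrc1, Nppb, Polg and Zap70 did so with animal numbers over 100 as a covariate. Akap6, C1qa, Cacna1g, Fabp4, Gja5, Lep, Mcm3, Mfap4, Mrc1, Nppb and Zap70 did so without the hypoxia animals numbered over 100. Abcc9, Cacna1g, Col5a1, Fabp4, Gja5, Lep, Lyz2, Mcm3, Mrc1, Nppb and Zap70 did so on the first technical array. Akap6, C1qa, Lep, Lyz2, Mcam, Mcm3, Mfap4, Mrc1, Myl7 and Polg did so without the 2 hypoxia arrays. Abcc9, Fabp4, Gja5, Lep, Lyz2, Mcam, Mfap4, Mrc1, Nppb and Polg did so with only the 2 groups fitted. Akap6, Cacna1g, Gja5, Lep, Lyz2, Mrc1, Nppb and Polg did so under quantile normalisation. Gja5, Lep, Lyz2, Mcm3, Mrc1, Nppb and Zap70 did so with animal weights. Abcc9, Aplnr, Mcm3, Mrc1, Myl7, Nppb and Polg did so on the highest-ratio probe. Akap6, Cacna1g, Gja5, Mcm3, Mrc1, Nppb and Zap70 did so without the least correlated animals. Gja5, Lyz2, Nppb and Polg did so with arrays centred. Fabp4, Gja5, Lep and Lyz2 did so with equal spread. C1qa, Mrc1, Myl7 and Nppb did so on probes with values on every array. Calls also ended for Lep and Mcm3 with a random block. List calls also ended for cell cycle with animal weights, with a random block and without the 2 hypoxia arrays, and macrophage on the first technical array.

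**Figure D3:**
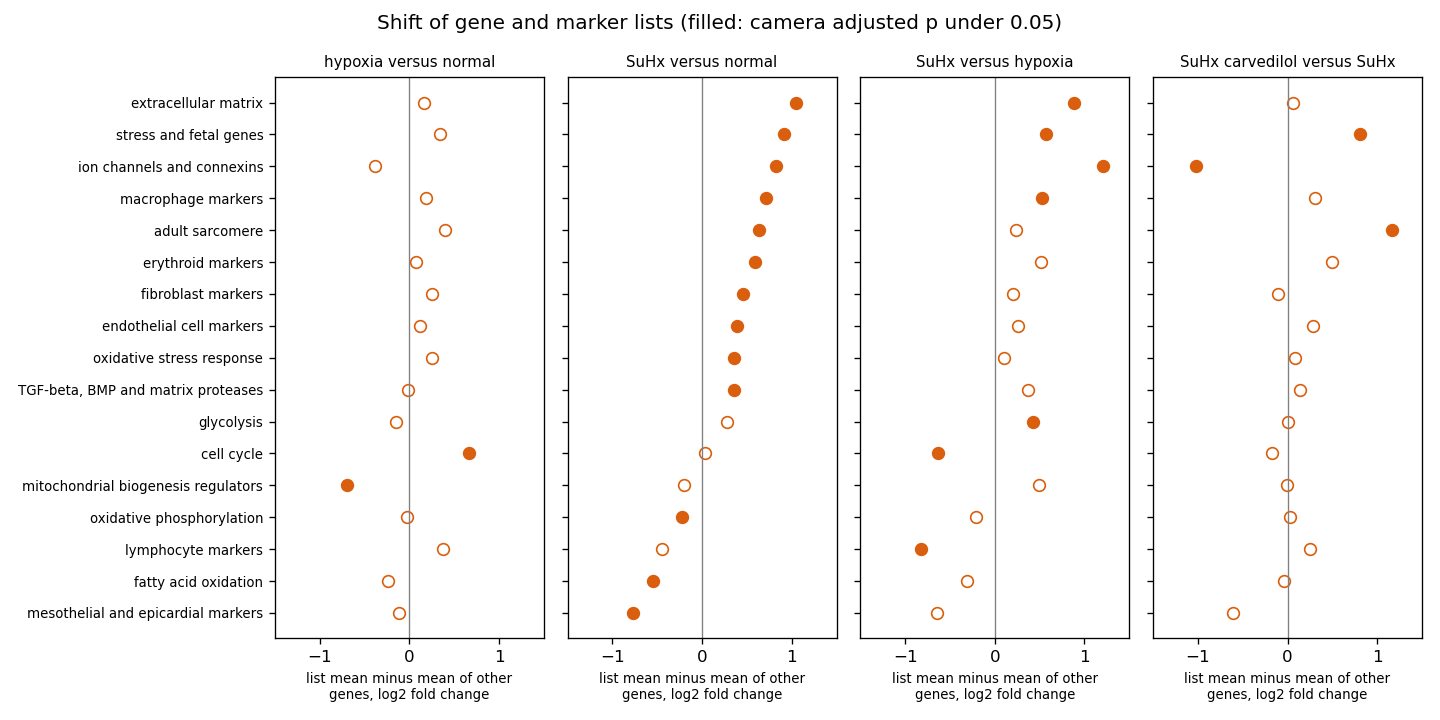
Mean log2 change of 17 lists minus the mean of all other tested genes in 4 comparisons, with filled points where the camera adjusted p was under 0.05. The adult sarcomere list lay at 0.64 in SuHx against normal and at 1.16 in carvedilol against SuHx, and the matrix list at 1.05 and 0.06.

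Carvedilol-treated SuHx ventricles held more RNA of contractile genes than untreated SuHx ventricles. Of 19 adult sarcomere genes 5 rose, none fell, and 9 rose adjusted over the list alone. They were cardiac troponin T (Tnnt2, 2.15 ± 0.36, adjusted p = 0.00944), the muscle creatine kinase Ckm (2.07 ± 0.31, adjusted p = 0.00491), tropomyosin Tpm1 (1.38 ± 0.24, adjusted p = 0.0132), cardiac troponin I (Tnni3, 1.96 ± 0.41, adjusted p = 0.0264) and Actc1. Sarcomere genes as a list had a shift of 1.16 (camera adjusted p = 1.26e-13, adjusted p = 0.136 with an estimated correlation), and of 0.56 with equal spread. Of 15 stress and fetal genes Ankrd1, Csrp3 and Xirp2 rose, all of which bind sarcomeric proteins, and 5 rose adjusted over the list alone. Ankrd1 changed by 1.28 ± 0.18 (adjusted p = 0.00354), Csrp3 by 1.89 ± 0.39 (adjusted p = 0.0251) and Xirp2 by 2.01 ± 0.46 (adjusted p = 0.0377, not in all animals). The shift of the stress list was 0.80 (camera adjusted p = 3.95e-06, adjusted p = 0.101 with an estimated correlation), and 0.44 with equal spread. Tnni3 lost its call without SuHx animal 1, 2, 3 or 5 or carvedilol animal 5 (adjusted p up to 0.0722) and Csrp3 without SuHx animal 1 or 5 or carvedilol animal 5 (adjusted p up to 0.069). Xirp2 lost its call without SuHx animal 1, 2, 3, 4 or 5 or carvedilol animal 1, 2, 3 or 5 (adjusted p up to 0.0936).

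Adrb1, a target of the drug, changed by -2.45 ± 0.40 (adjusted p = 0.0073). Of 23 adrenergic genes it alone was called, and 3 fell adjusted over the list alone (camera adjusted p = 0.182, fry adjusted p = 0.00306, passed by 6 of 33 lists). Of 11 ion channels and connexins Hcn2 fell, and 4 fell adjusted over the list alone, with a shift of -1.02 (camera adjusted p = 0.00764, adjusted p = 0.26 with an estimated correlation). That call ended on the highest-ratio probes (adjusted p = 0.0618) and on probes with values on every array (adjusted p = 0.344). Hcn2 changed by -1.59 ± 0.38 (adjusted p = 0.0487), which was lost without any animal but carvedilol 3 (adjusted p up to 0.121). Of 27 fatty acid oxidation genes the electron carrier Etfa fell (-1.95 ± 0.35, adjusted p = 0.014), also adjusted over the list alone. Etfa lost its call in 6 other settings, among them its highest-ratio probe (-1.09, adjusted p = 0.253). Of 30 matrix genes Col5a3 fell, and 4 fell adjusted over the list alone, with the list at a shift of 0.06 (camera adjusted p = 0.972). Col5a3 changed by -1.67 ± 0.39 (adjusted p = 0.0455), which was lost without any animal but carvedilol 1 or 5 (adjusted p up to 0.0912). Postn stood at -2.17 ± 0.64 (5 SuHx animals, adjusted p = 0.109). The NF-kappaB inhibitor Nfkbia rose by 1.41 ± 0.27 (adjusted p = 0.0171), which was lost without SuHx animal 5 (adjusted p = 0.0504).

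Among markers of other cells Krt18 fell (-0.92 ± 0.17, adjusted p = 0.0162), 1 of 6 mesothelial and epicardial markers and 1 of 2 adjusted over the list alone (camera adjusted p = 0.0762). No marker of macrophages (shift 0.30, camera adjusted p = 0.122) or fibroblasts (shift -0.10, camera adjusted p = 0.972) was called. Extreme changes by the fixed rule were those of Pcdha4 (-3.49 ± 0.49, 4 animals per group, adjusted p = 0.00655) and L3hypdh (-3.11 ± 0.56, 4 carvedilol animals, adjusted p = 0.0162). The neuropeptide gene Vip rose by 2.95 ± 0.60 (5 carvedilol animals, adjusted p = 0.0246), which was lost without SuHx animal 3 or 5 or carvedilol animal 1 (adjusted p up to 0.069). Nppa (1.56 ± 0.41, adjusted p = 0.0683), Myh7 (1.66 ± 0.43, adjusted p = 0.0617) and Nppb (0.33 ± 0.41, adjusted p = 0.736) did not pass. Nor did Igf1 (-0.79 ± 0.25, adjusted p = 0.125), Atp2a2 (0.24 ± 0.17, adjusted p = 0.515) and Col1a1 (-0.64 ± 0.33, adjusted p = 0.336).

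In all, 91 genes were called between carvedilol and SuHx, 30 higher and 61 lower, with 1639 at an unadjusted p under 0.05 and all animals on their own side in 87. The count fell to 28, 35, 32, 20 and 49 without SuHx animal 1, 2, 3, 5 or 6 and to 47 without carvedilol animal 5. On the first technical array of each animal 1 gene was called, and in a fit of only these 2 groups 11. Of the 91 genes 33% were higher, but 72.7% of the 11, 53.2% on probes with values on every array and 53.1% without SuHx animal 3. All 6 carvedilol animals and 2 hypoxia animals carried animal numbers over 100, and the labels do not say what these numbers mark. With numbers over 100 as a covariate the sarcomere list had a shift of 0.82 (camera adjusted p = 0.037) and Adrb1 a change of -1.70 (adjusted p = 0.276). The stress list then had a shift of 0.64 (camera adjusted p = 0.15) and the ion channel list one of -0.72 (camera adjusted p = 0.588). Of 115 genes called with the covariate 7 were shared with the 91, and the balance reversed to 92 higher and 23 lower.

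Adrb1, Ankrd1, Ckm, Col5a3, Csrp3, Etfa, Hcn2, Krt18, Nfkbia, Tnni3, Tnnt2, Tpm1, Vip and Xirp2 lost their calls on the first technical array. Adrb1, Col5a3, Csrp3, Etfa, Hcn2, Krt18, L3hypdh, Nfkbia, Pcdha4, Tnni3, Tnnt2, Vip and Xirp2 did so with only the 2 groups fitted. Adrb1, Ckm, Col5a3, Csrp3, Etfa, Hcn2, Krt18, L3hypdh, Tnni3, Tpm1, Vip and Xirp2 did so with animal numbers over 100 as a covariate. Col5a3, Csrp3, Hcn2, Tnni3 and Xirp2 did so without the least correlated animals. Col5a3, Hcn2, Krt18 and Xirp2 did so with values of 2 animals per group. Csrp3, Krt18, Tnni3 and Xirp2 did so with equal spread. Col5a3, Hcn2, Tnni3 and Xirp2 did so with the replicate number as a block. Etfa, Hcn2 and Krt18 did so on the highest-ratio probe. Calls also ended for Etfa and Hcn2 with a random block, Col5a3 and Krt18 under quantile normalisation, Hcn2 with arrays centred, Col5a3 without the hypoxia animals numbered over 100, and Etfa on probes with values on every array.

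Against normal ventricle the carvedilol group had more RNA of contractile and stress genes, with the largest shifts of these lists among the 5 comparisons. Of 19 sarcomere genes 11 rose, and 14 adjusted over the list alone (shift 1.80, camera adjusted p = 6.85e-21, adjusted p = 0.0146 with an estimated correlation, shift 0.91 with equal spread). Of 15 stress and fetal genes 11 rose, with the same number adjusted over the list alone (shift 1.71, camera adjusted p = 4.17e-18, adjusted p = 0.000319 with an estimated correlation). Nppb was 3.09 ± 0.41 higher (adjusted p = 0.000107) and Myh7, the slow myosin heavy chain, 2.91 ± 0.43 (adjusted p = 0.000227). Nppa was 1.45 ± 0.41 higher (adjusted p = 0.025), which was lost without normal animal 5 or carvedilol animal 3 or 5 (adjusted p up to 0.0707). Adrb1 changed by -2.15 ± 0.40 (adjusted p = 0.0015, but 0.282 with animal numbers over 100 as a covariate) and Apln, the apelin gene, by -1.90 ± 0.34 (adjusted p = 0.00122). Myh6 (-0.26 ± 0.68, adjusted p = 0.848), Atp2a2 (-0.02 ± 0.17, adjusted p = 0.948) and Col1a1 (-0.25 ± 0.33, adjusted p = 0.677) did not pass.

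Matrix and macrophage lists were higher in the carvedilol group than in normal ventricle, and fatty acid oxidation and oxidative phosphorylation were lower relative to other genes. Of 30 matrix genes 5 rose and Col5a3 fell, with 9 and 1 adjusted over the list alone (shift 1.11, camera adjusted p = 9.16e-10, adjusted p = 0.163 with an estimated correlation). Of 16 macrophage markers C1qa, Ctss, Lyz2 and C1qb rose, with the same number adjusted over the list alone (shift 1.02, camera adjusted p = 3.86e-08, adjusted p = 0.0146 with an estimated correlation). Of 27 fatty acid oxidation genes 10 fell and none rose, with 12 lower adjusted over the list alone (shift -0.58, camera adjusted p = 0.000165, adjusted p = 0.378 with an estimated correlation). Of 35 oxidative phosphorylation genes 9 fell and 2 rose, with 14 and 2 adjusted over the list alone (shift -0.21, camera adjusted p = 0.0184, adjusted p = 0.631 with an estimated correlation). This last call was lost without normal animal 2 or carvedilol animal 1 (adjusted p up to 0.182), and the shift moved to -0.083 without the latter and to -0.67 with equal spread. Of 6 mesothelial and epicardial markers Msln, Krt8 and Krt18 fell, and 4 adjusted over the list alone (shift -1.38, camera adjusted p = 0.00217, adjusted p = 0.0738 with an estimated correlation). Of 7 erythroid markers Alas2 and Hbb-b1 rose, with the same number adjusted over the list alone (shift 1.08, camera adjusted p = 0.00129, adjusted p = 0.0146 with an estimated correlation).

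The other 6 lists that passed lay above the remaining genes. Of 17 endothelial markers 3 rose and 1 fell, with 4 and 1 adjusted over the list alone (shift 0.67, camera adjusted p = 0.00148, adjusted p = 0.248 with an estimated correlation). Of 22 hypoxia-inducible targets 3 rose, with 4 higher and 1 lower adjusted over the list alone (shift 0.50, camera adjusted p = 0.00565, adjusted p = 0.163 with an estimated correlation). Of 26 TGF-beta, BMP and matrix protease genes 2 rose and 1 fell, with the same numbers adjusted over the list alone (shift 0.50, camera adjusted p = 0.00294, adjusted p = 0.326 with an estimated correlation). None of 16 immediate early genes was called, nor adjusted over the list alone (shift 0.46, camera adjusted p = 0.0247, adjusted p = 0.378 with an estimated correlation). That call was lost without normal animal 1 or carvedilol animal 1 (adjusted p up to 0.0956). Of 23 cytokines and adhesion molecules 3 rose and 4 fell, with the same numbers adjusted over the list alone (shift 0.42, camera adjusted p = 0.0356, adjusted p = 0.248 with an estimated correlation). They lost their call without normal animal 5 or 6 or carvedilol animal 1 or 3 (adjusted p up to 0.0624). Of 10 smooth muscle and pericyte markers 1 rose, also adjusted over the list alone (shift 0.58, camera adjusted p = 0.0394, adjusted p = 0.119 with an estimated correlation). This call was lost without normal animal 1 or 5 or carvedilol animal 2 or 3 (adjusted p up to 0.0802).

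In all, 14 of 33 lists passed camera in this comparison and 4 with an estimated correlation. With animal numbers over 100 as a covariate 9 of the 14 lost their call, and the endothelial list turned to a shift of -0.077 and the erythroid list to one of -0.17. There were 1077 called genes, 222 higher and 855 lower, with 2596 at an unadjusted p under 0.05. The same covariate gave 263 called genes, 143 higher and 120 lower, of which 124 were shared with the 1077.

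The TGF-beta, cytokine, endothelial, erythroid, hypoxia-inducible targets, immediate early, mesothelial, oxidative phosphorylation and smooth muscle lists lost their calls with animal numbers over 100 as a covariate. The TGF-beta, cytokine, hypoxia-inducible targets, immediate early, oxidative phosphorylation and smooth muscle lists did so on probes with values on every array. The cytokine, immediate early and smooth muscle lists did so with values of 2 animals per group. The endothelial, mesothelial and smooth muscle lists did so under quantile normalisation. List calls also ended for endothelial and smooth muscle with equal spread, oxidative phosphorylation on the highest-ratio probe, with animal weights and without the least correlated animals, and smooth muscle with the replicate number as a block and without the 2 hypoxia arrays. Nppa lost its call with equal spread, under quantile normalisation, on the first technical array and with animal numbers over 100 as a covariate.

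Hypoxia and SuHx, both set against the same normal animals, shared 24 called genes of the same direction, 5 higher and 19 lower, and none of opposite direction. The genes higher in both were Nppb, Cyp1a1 (2.15 ± 0.62 in hypoxia, adjusted p = 0.0257), Cebpd, Hspb3 and Plod2, of which the last 3 were chosen after their values were seen. Independent lists of these sizes would share 0.338 higher and 6.21 lower genes. With the normal animals split 3 and 3, the median over 20 splits was 0 (0 to 3), at medians of 400.5 and 9.5 called genes. So few in SuHx left little room for overlap. A fit of only SuHx and normal called 440. Across genes the changes correlated with r = 0.33, against 0.27 in simulations of unchanged groups sharing the same normal animals and 0.19 with split animals. Their covariance was 0.17 against a simulated 0.0693. Genes are not independent replicates.

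Of the 92 genes called in SuHx against normal, 3 were called in the opposite direction in carvedilol against SuHx, namely Fgfbp1, Pcdha4 and Ran. Another 3 were called in the same direction again, Ccnd2, Krt15 and Krt18. Those outside the fixed rule were chosen after their values were seen. Fgfbp1 changed by -2.24 ± 0.48 in SuHx against normal (4 SuHx animals, adjusted p = 0.0332), a call lost without normal animal 1, 2, 4, 5 or 6 or SuHx animal 4 or 5 (adjusted p up to 0.118), with values asked of 2 animals per group and without the least correlated animals. In carvedilol against SuHx it changed by 2.51 ± 0.50 (5 carvedilol and 4 SuHx animals, adjusted p = 0.0246), which was lost without SuHx animal 4 or 5 or carvedilol animal 5 (adjusted p up to 0.069) and with only the 2 groups fitted (adjusted p = 0.12). Pcdha4 lost its call in carvedilol against SuHx with only the 2 groups fitted, and in SuHx against normal with the animal as a random block and without the least correlated animals. Independent lists would give 0.403 reversals, and the 20 splits of the SuHx animals gave a median of 0 (0 to 1), at a median of 15.5 genes called in SuHx against normal. The covariance of the changes across genes was -0.112, against -0.133 in simulations in which carvedilol had no effect and the SuHx animals were shared.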

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

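Tests of scaling between arrays, of animal numbers, of single outlying animals, of the aryl hydrocarbon receptor and without 2 hypoxia arrays were chosen only after the result was seen. The scalings and the animal numbers had been fixed before as settings, but not as explanations of these patterns, and for the 2 arrays the prediction was written before the value was known.

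Of 1212 genes called in hypoxia against normal 1125 were lower, while hypoxia arrays held fewer values. Without the 2 with the fewest values 89.1% of calls were lower, which argues against these as sole source. Scaling stays open, as 3 forms (lowest share 81.2%) left the median change at -0.38 to -0.29. Relative to the median change, other probes of the same genes moved by 32.7% of the called probes' fall (95% interval 24.3 to 40.1). For 683 called probes of 581 genes, 67.8% of others lay below the median. Called probes were chosen by their fall, so a fall of the transcripts and probe-specific hybridization cannot be told apart. Hypoxia itself as a source was not tested separately.

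Contractile genes were higher in carvedilol than in SuHx ventricles, with a list mean of 0.94. This lay at percentile 100 of 10000 random lists matched for level (maximum 0.68). Equal spread lowered the list's shift, so wider spread on the carvedilol arrays may add to it. All carvedilol animals but no SuHx animal had numbers over 100. Within hypoxia, 2 animals with such numbers differed from the 4 others by 0.29, which is 31.2% of 0.94. With so few animals, effects of the drug, longer time after hypoxia, spread and whatever the numbers mark cannot be told apart.

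Cyp1a1 was higher in SuHx with and without carvedilol. All 12 animals given SU5416 lay above the highest normal animal, which argues against single outlying animals. Of 4 other tested targets of the aryl hydrocarbon receptor 0 were called higher in SuHx against normal, with Cyp1b1 at 1.96 ± 0.63 (adjusted p = 0.138), Nqo1 at -0.34, Aldh3a1 at -0.61 and Ugt1a6 at 0.70. Cyp1b1 was higher in SuHx than in hypoxia (2.37, adjusted p = 0.0165) and in carvedilol than in normal ventricle (3.64, adjusted p = 0.000853). Activity of the receptor, with 0 of 4 targets called, remained open, and Cyp1a1 rested on 1 probe.

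Single animals lay far from the other animals of their group in 60 of 696 groups of values examined, over 33 lists, 140 genes and the number of spots with a value in 4 groups. Chance alone marks about 1 in 20 groups, or 34.8 here, and genes of 1 animal are not independent. All values that follow are log2 ratios of such an animal, with list values as means of the list.

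Normal animal 1 lay far from the others of its group in Postn (-0.97) and Nqo1 (-3.39), animal 2 in Scyl2 (-6.29), and animal 3 in the matrix list (-0.74) and Perm1 (2.22). Normal animal 4 did so in the adipocyte list (2.39), Ryr2 (4.18) and Fabp4 (5.50), and animal 5 in Nppb (-0.56). For normal animal 6 these were the cell cycle list (-0.41), the lymphocyte list (-0.62), Rxrg (7.35), Polrmt (0.57), Ucp3 (2.09), Mcm3 (-3.13) and Krt8 (-4.26).

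Hypoxia animal 3 lay apart in Aplnr (-3.08), Pfkp (-3.05), Plod2 (-0.39) and Ugt1a6 (-6.26). Hypoxia animal 4 did so in the lymphocyte list (-0.22), Rxrg (2.23), Got1 (-1.99) and Ctss (-1.96). In hypoxia animal 5 the values were those of Tnni1 (-3.57), Krt18 (-4.21), Mrc1 (-2.74) and L3hypdh (-1.55). In hypoxia animal 6 they were those of the biogenesis list (-1.36), the fibroblast list (0.55), Polg (-4.89) and Prkar1a (-0.69).

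SuHx animal 1 lay apart in the renin-angiotensin, endothelin, natriuretic and nitric oxide list (0.16) and in Slc14a1 (-0.92), animal 2 in Mcam (0.50) and Cyp1b1 (-2.60), and animal 3 in the circadian clock list (0.61) and Enah (1.46). SuHx animal 4 did so in Myh6 (0.52) and Kcnh2 (1.84), and animal 5 in Decr1 (2.99). For SuHx animal 6 the values were those of Nppb (5.58), Nrap (7.61), C1qc (5.40), C1qa (7.17) and Aldh3a1 (-4.91).

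Carvedilol animal 1 lay apart in the TGF-beta list (0.45), Atp2a2 (1.06), Ppargc1b (3.45), Rxrg (2.87), Got1 (0.53), Ndufv1 (1.49), Jph2 (0.17) and Mcam (5.57). Carvedilol animal 3 did so in the list of hypoxia-inducible targets (-0.32) and Fbln1 (0.84), and animal 5 in Tceal7 (-1.32). In carvedilol animal 6 the values were those of Gpi (0.36), Slc14a1 (-1.12) and Cldn5 (5.72).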

How the results depend on the processing

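Tests without the 2 hypoxia arrays with the fewest values and without the least correlated animal of each group were chosen only after the result was seen; the other settings were fixed before. Counts of called genes moved by over 1.5 times as follows, and the cause was not tested unless the setting itself gives it. In hypoxia against normal (1212) there were 1861 with equal spread, 801 with values asked of 2 animals per group, 797 with values on every array, 2308 probes at probe level and 672 with only the 2 groups fitted. In SuHx against normal (92) there were 235 with quantile normalisation, 313 with equal spread, 14 on the first technical array, 45 with 2 animals per group, 259 with values on every array, 153 on the highest-ratio probe, 1036 with animal weights, 239 with the animal as a random block, 148 at probe level, 440 with only the 2 groups fitted, 147 with hypoxia animals numbered under 100, 43 with the replicate number as a block, 217 without the 2 hypoxia arrays and 10 without the least correlated animals. In SuHx against hypoxia (1131) there were 2340 at probe level and 599 with only the 2 groups fitted. In carvedilol against SuHx (91) there were 143 with equal spread, 1 on the first technical array, 42 with 2 animals per group, 388 with animal weights, 338 with the animal as a random block, 287 at probe level, 11 with only the 2 groups fitted, 57 with the replicate number as a block, 186 without the 2 hypoxia arrays and 53 without the least correlated animals. In carvedilol against normal (1077) there were 444 on the first technical array, 2258 with animal weights, 263 with animal numbers over 100 as a covariate and 2053 at probe level. At probe level more units were tested, and on every array fewer.

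Against 39 list calls there were 59 with equal spread, 23 with values on every array and 6 with an estimated correlation. The overlap of hypoxia and SuHx (24) was 0 with split normal animals, 95 with quantile normalisation and 52 with the random block, and the reversals by carvedilol (3) were 0 with split SuHx animals and 13 with the random block. On the highest-ratio probe Adra1b (0.0051) and Cpt1b (0.76) in hypoxia against normal, Cpt1b (-0.22), Ldb3 (-0.050) and Mcm3 (0.034) in SuHx against hypoxia and Atp2a2 (0.85) in carvedilol against normal changed sign. Other genes that did were Fabp4 (-0.10, equal spread) and Krt18 (0.17, quantile normalisation) in hypoxia against normal and Myh6 (1.87, values on every array) in carvedilol against normal. Among called lists the shifts of the endothelial (-0.077) and erythroid (-0.17) lists in carvedilol against normal did so with animal numbers over 100 as a covariate, where neither passed. Lists not called that did, with a call there, were sarcomere in hypoxia against normal (-0.57) and calcium handling in carvedilol against normal (-0.50) with equal spread, cell cycle in carvedilol against normal (0.48, quantile normalisation), and in carvedilol against SuHx oxidative phosphorylation (-0.22 with equal spread, -0.21 on the first technical array) and endoplasmic reticulum stress (-0.41 with animal numbers over 100 as a covariate).

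Omission of 1 animal gave 816 to 1227, 31 to 132, 782 to 1151, 20 to 104 and 737 to 1048 genes in the 5 comparisons in this order, and 34 to 42 lists. Named called genes kept direction and threshold in 2250 tests with 1 animal left out and 2862 with another setting, lost the threshold in 546 and 698 and turned in 0 and 7; called lists kept both in 428 and 535 and lost the threshold in 40 and 89. Animals with the same replicate number shared only a number, since 4 of 36 pairs of deviations correlated over 0.1 (median 0.003, -0.26 to 0.18) and 9 were best with their own number. The other deposited table holds the same values and was not run. Signal over background was not analysed here, so what it limits is unknown.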

Other observations

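Tests of the aryl hydrocarbon receptor, single animals, scaling and animal numbers in the closing parts were chosen only after the result was seen.

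Genes of the circadian clock, a list of 12, differed between groups without a shift of the list as a whole. In SuHx against normal, Bmal1, a core activator of the clock, was 2.11 ± 0.36 higher (limma adjusted p = 0.00579), its output Dbp changed by -1.55 ± 0.30 (adjusted p = 0.0131) and the repressor Per2 by -1.16 ± 0.24 (adjusted p = 0.0184; lost without normal animal 3 or 4, adjusted p up to 0.0643), the same 3 adjusted over the list alone. All 3 calls were lost without the least correlated animal of each group, those of Dbp and Per2 also on the first technical array, that of Per2 with the animal as a random block and that of Bmal1 with values asked of 2 animals per group. Bmal1 (1.43 ± 0.36, adjusted p = 0.0124), Per1 (1.55 ± 0.40, adjusted p = 0.0147) and Nr1d1 (1.41 ± 0.42, 5 hypoxia animals, adjusted p = 0.0328) were also higher in SuHx than in hypoxia, and Dbp changed by -0.95 ± 0.30 (adjusted p = 0.0446). Nr1d1 lost this call in 5 of 12 omissions of 1 animal (adjusted p up to 0.0659; 0.87 without hypoxia animal 3) and Dbp in 6 (adjusted p up to 0.112), and each also in 6 other settings. Bmal1 and Per1 lost theirs with values asked of 2 animals per group, with only the 2 groups fitted and without the least correlated animals, and Per1 moved to 0.65 in the first of these. In hypoxia against normal, Per1, Nr1d1 and Per2 fell, with Per2 at -0.86 ± 0.24 (adjusted p = 0.0206). There Per1 lost its call in 3 and Nr1d1 in 6 of 12 omissions, and in other settings Per1 in 8, Nr1d1 in 7 and Per2 in 5, with Per2 at -0.51 without the 2 hypoxia arrays with the fewest values. The camera adjusted p of the list was 0.804 in SuHx against normal, 0.949 in SuHx against hypoxia and 0.726 in hypoxia against normal, and no clock gene was called in carvedilol against SuHx, where Bmal1 stood at -1.24 ± 0.36 (adjusted p = 0.1). The hour at which animals were killed is not given in the sources used here.

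No tested member of the list of hypoxia-inducible targets was called higher after 4 weeks of hypoxia than in normal ventricle. Of 22 tested targets 7 had a positive change, 21 were not called and Ddit4 fell (-1.58 ± 0.45, 4 hypoxia animals, adjusted p = 0.0262; lost without normal animal 2 or 6 or hypoxia animal 5), also adjusted over the list alone, and the list had a shift of 0.19 (camera adjusted p = 0.727). The carbonic anhydrase Car9 (-0.01 ± 0.41, adjusted p = 0.992), the prolyl hydroxylase Egln3 (-0.18 ± 0.25, adjusted p = 0.677) and Bnip3 (0.66 ± 0.36, adjusted p = 0.248) did not pass. Egln3 (1.10 ± 0.25, adjusted p = 0.00572) and Ddit4 (2.01 ± 0.45, 4 hypoxia animals, adjusted p = 0.00639) were higher in SuHx, sampled 2 weeks after the return to sea level, than in hypoxia. Ddit4 moved there to 1.32 without hypoxia animal 5 and lost its call on the first technical array (adjusted p = 0.0958) and with only the 2 groups fitted. Its fall in hypoxia against normal lost the call in 6 other settings and moved to -0.89 without hypoxia animal 5.

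Chance as the source of the number of called genes was examined with 100 splits of the animals of each comparison, the real one included. In each comparison 1 of the 100 splits, the real one, called as many genes as were found. Chance alone therefore seldom gave such counts, but the splits do not show which of the called genes are false. The real counts and the highest of the other splits were 1212 and 128 in hypoxia against normal, 92 and 1 in SuHx against normal, 1131 and 70 in SuHx against hypoxia, 91 and 4 in carvedilol against SuHx, and 1077 and 83 in carvedilol against normal.

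Arrays of 1 animal had a median r of 0.963 in normal (3 pairs) and 0.886 in hypoxia (9 pairs). It was 0.941 in SuHx (12 pairs) and 0.741 in carvedilol (3 pairs, all of animal 3). The lowest r of any pair, 0.477, lay in hypoxia.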
